A study of Mus musculus with 6 samples.

How the data were processed

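The series holds JARID2 PAR-CLIP of E14 mouse embryonic stem cells, 3 libraries of untreated cells and 3 of cells given 2 µM retinoic acid for 24 h. Per the labels, cells were pulsed with 500 µM 4-thiouridine for 2 h and irradiated at 312 nm with 400 mJ/cm2 before immunoprecipitation of JARID2. The authors deposited 1 list of RNA contact sites per condition, named for libraries b1 to b3 together, so there is no value per library, and no test between conditions with replicates could be made.

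Each deposited list gives a chromosome, start, end, strand, read-group name and a whole-number score per site. The unit of the values is the authors' score as deposited, whose meaning is not given in the sources used here. It runs from 1 to 480704 untreated and 448416 treated, and the number of sites jumps at a score of 10. Bowtie and the mm9 build are named per the submitters' processing notes. The role, version and parameters of Bowtie and the program that called the sites are not given in the sources used here. Read depth is therefore unknown, and the number of sites per list is the depth used for intervals.

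Sites were read from the lists and all were kept. A site was shared when it overlapped a site of the other list by at least 1 base on the same strand. Chance overlap came from 1000 seeded placements of the treated sites, keeping length, chromosome and strand, either between the first and last site of the chromosome or within the 10-kb window around the site. The alternative that required 50% of both sites to be shared used 100 placements. Sites of both lists together were joined into regions across gaps of up to 10 kb on 1 strand. Coordinates are written from 1. Regions with at least 10 sites were compared by a two-sided Fisher exact test of sites inside against outside the region, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 odds ratios are treated over untreated. Each SE printed with them is that of the natural log odds ratio, so it understates the SE on the log2 scale. Scores and lengths of shared and unshared sites were compared by a two-sided permutation test of medians with 100000 resamples. Equal list length was reached with 1000 random draws of untreated sites. Intervals are exact 95% intervals and cover counting error only.

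The reference at hand was the GENCODE M21 annotation of a later build, so nuclear coordinates were not converted and nuclear genes were not named. The mitochondrial annotation was used, on the assumption that both builds hold the same mitochondrial record, and was checked by the presence of a T in every site against shifted coordinates. A site over adjoining genes that overlap counts for each. Of 22 gene lists fixed beforehand, 1, the mitochondrially encoded genes, could be run. Matching nuclear regions to transcripts by the requirement of a T in every site was tried and left out, since many transcripts met it for each region.

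The rule for naming, set before the data were examined, took the 10 regions with the most sites in each list, the 5 with the most sites in 1 list and 0 in the other, the 5 with the lowest Fisher exact p in each direction, up to 4 members with a site per gene list, and Meg3, Rian, Mirg and Jarid2. Regions named outside the rule are said to be so. Taking called regions out of the chromosome shares, score minimums of 10, 100 and 1000, and a treated minimum of 10 set against an untreated minimum of 18.0, from the score ratio at loci scored at least 1000, were chosen after the data were seen.

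The tests were tested on simulated data. In 20 runs with 20 regions changed 4-fold, 98.5% were recovered with 0.35 false calls per run. These rates belong to the simulated changes and were not split by region size or direction. They cannot be carried over to small regions, to losses or to sites clustered on the same transcript. An overlap made at 30.0% was found as 30.7%. Of 100 null tests, 2 had p under 0.05, and overlaps of 300 sites recounted by direct comparison gave 0 differences. Alternatives were a reciprocal overlap, a distance of up to 100 bases, ignoring strand, the higher-scored 50% of each list, joining sites up to 50 bases apart, leaving out the mitochondrial chromosome and unplaced contigs, gaps of 1 and 100 kb, minimum numbers of sites, and leaving out the region with the most sites. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.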

Results

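The authors' list of RNA contact sites of JARID2, a partner protein of the Polycomb complex PRC2, was far shorter after retinoic acid than before. Read depth and the calling of sites are unknown, so list length alone does not show a change in contact. In E14 cells, a line of mouse embryonic stem cells, the authors' list for untreated cells held 23380 RNA contact sites, and the list for cells given 2 µM retinoic acid for 24 h held 5348, a ratio of 4.37. Each list pools 3 libraries, so n is 1 list per condition, the lists give no spread between replicates, and the comparisons below are between pooled lists. Sites came from PAR-CLIP, in which cells take up 4-thiouridine (500 µM for 2 h), are irradiated at 312 nm and are lysed for immunoprecipitation of JARID2. Intervals are 95% exact binomial or Fisher exact intervals and cover counting error only.

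The gap between the lists lay mostly among sites with low scores. Sites with a score of at least 10 numbered 21533 untreated and 5142 treated, a ratio of 4.19. With a score of at least 100 there were 1891 and 1086, a ratio of 1.74, and with a score of at least 1000 there were 508 and 333, a ratio of 1.53. The median score was 17 (interquartile range 12 to 30) in the untreated list and 23 (14 to 70) in the treated list. Summed scores were 6580243 and 4702962, a ratio of 1.40, over 346 kb and 74.0 kb of covered sequence. The 10 highest-scored sites carried 24.9% of the untreated sum and 34.6% of the treated sum. Sites had a median length of 12 bases in both lists. What the deposited score counts is not given in the sources used here, so read depth per library is unknown.

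**Figure D1:**
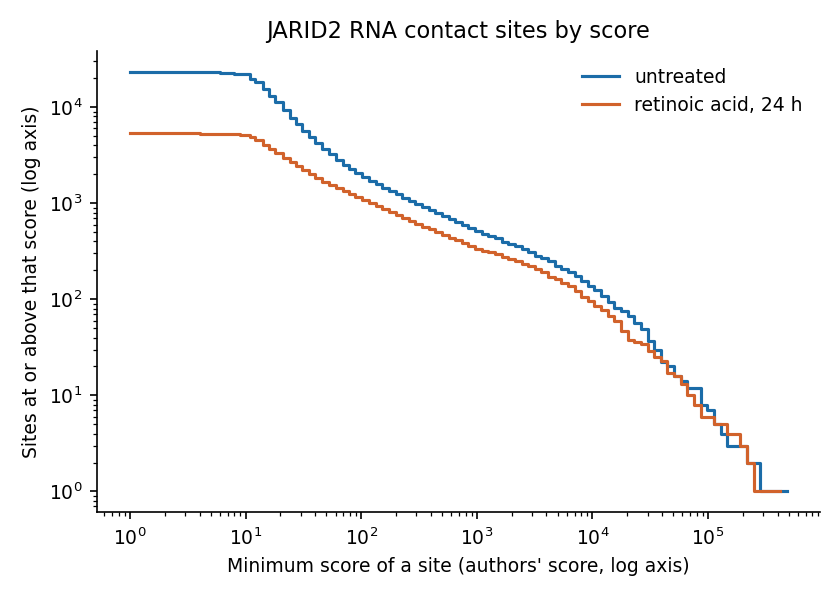
Number of JARID2 RNA contact sites (vertical log axis) at or above each value of the authors' score (horizontal log axis) for the pooled untreated and retinoic acid lists. The lines are furthest apart at low scores, with 21533 and 5142 sites at a score of at least 10, and lie closer at a score of at least 1000, with 508 and 333.

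Part of the treated list lay where the untreated list also had sites. Of the 5348 treated sites, 1462 (27.3%, interval 26.1 to 28.6) shared at least 1 base on the same strand with an untreated site, and 1468 of 23380 untreated sites (6.28%, 5.97 to 6.60) shared 1 with a treated site. Random placement of the treated sites on their chromosomes gave 2.29% on average, and random placement within 10 kb around each site gave 4.94%, with a highest value of 5.70%. The permutation p was 0.001 for both, the smallest that 1000 placements can give. Without the mitochondrial chromosome and unplaced contigs, 25.0% of treated sites were shared, against 0.0148% and 3.04% by chance.

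Sharing rose with the score. Among treated sites scored 10 to 19, 6.37% were shared, and among those scored 1000 or more, 81.4% were. The same bins of untreated sites gave 1.10% and 67.5%. Shared untreated sites had a median score of 144 and unshared ones 16, and in the treated list the medians were 115 and 18. The two-sided permutation p was 1e-05 for each list, the smallest that 100000 resamples can give. Shared sites had a median length of 13 bases in both lists, against 12 for unshared untreated sites (permutation p = 0.07) and 11 for unshared treated sites (permutation p = 1e-05, the smallest possible). Sites are not replicates, so these p-values describe the lists and not the conditions.

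**Figure D2:**
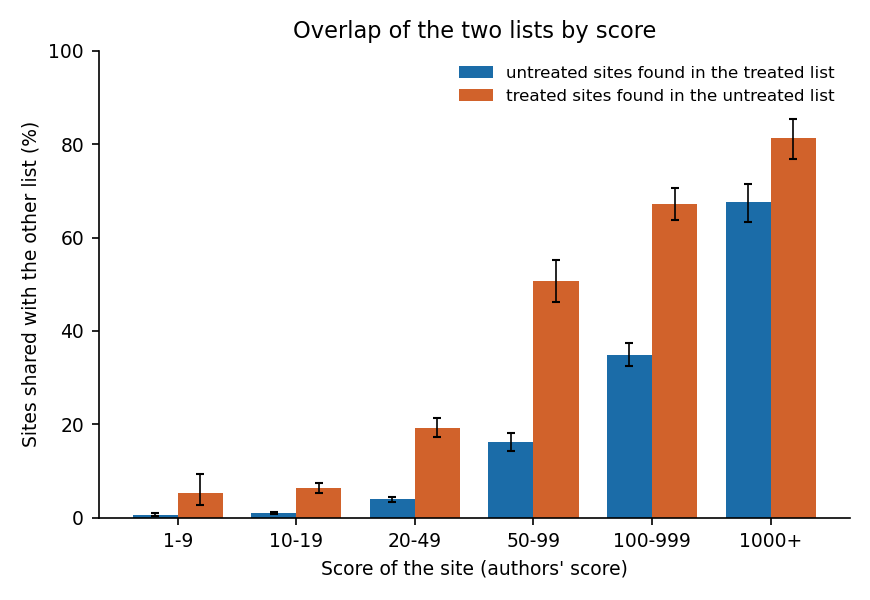
Percent of sites (vertical axis) that overlap a site of the other list on the same strand, by the authors' score (horizontal axis), with 95% exact binomial intervals as error bars. From scores of 10 to 19 to scores of 1000 or more, the shared percent went from 6.37 to 81.4 in the treated list and from 1.10 to 67.5 in the untreated list.

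Joined across gaps of up to 10 kb on 1 strand, the sites formed 9482 regions, of which 1928 held sites of both lists, 6364 held untreated sites only and 1190 held treated sites only. Of the regions with a treated site, 61.8% also held an untreated site, and of those with an untreated site, 23.3% held a treated one. Random draws of 5348 untreated sites held 3039 regions on average (range 2941 to 3152 over 1000 draws), and the treated list held 3118. The treated number lay within the range of the draws. At that equal length, 6.42% of treated sites on average (range 5.53 to 7.35 over the draws) were shared with the drawn untreated sites. With the 5348 highest-scored untreated sites in place of a random draw, 22.5% were shared and 2180 regions were held.

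Relative to list length, 18 regions held a different share of sites in the treated list. A two-sided Fisher exact test of each of 489 regions with at least 10 sites, with Benjamini-Hochberg adjustment, found 11 regions with a larger share of the treated list and 7 with a smaller share. Regions with p under 0.05 before adjustment numbered 56. The 11 regions spanned 0.861 to 15.4 kb (median 5.81 kb) and held 728 untreated and 590 treated sites. The 7 regions spanned 26.2 to 136 kb (median 87.8 kb) and held 663 untreated and 24 treated sites. The mean score per untreated site had a median of 151 over the 11 regions (12.2 to 17413) and 30.3 over the 7 (21.9 to 41.6). The losses thus lay mainly among low-scored sites, where the lists differed most. Neither span nor score was tested against direction over all regions. Nuclear regions are given by mm9 coordinates, because no gene annotation of that build was used. Regions were also tested, where at least 10 sites were left, with treated sites scored at least 10 against untreated sites scored at least 18.0. This setting, called the raised minimum below, was meant to match the lower treated scores at loci scored at least 1000.

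Among nuclear regions, the gain in share with the lowest p was on the plus strand of chromosome 17 from 39979968 to 39985776. It held 106 untreated and 91 treated sites, a log2 odds ratio of 1.93 (natural-log SE 0.14, Fisher exact adjusted p = 1.82e-16), and carried 19.5% and 23.3% of all score. With the raised minimum the same sites gave a log2 odds ratio of 0.94 (Fisher exact adjusted p = 6.91e-04). On the minus strand of chromosome 19, the region from 5796096 to 5802614 held 122 and 93 sites, with a log2 odds ratio of 1.76 (natural-log SE 0.14, Fisher exact adjusted p = 1.08e-14), and of 0.77 with the raised minimum (Fisher exact adjusted p = 0.00733). On the minus strand of chromosome 1, from 24618469 to 24623003, there were 84 and 57 sites, with a log2 odds ratio of 1.58 (natural-log SE 0.17, Fisher exact adjusted p = 1.48e-07), but its call was lost with the raised minimum, at 0.60 (Fisher exact adjusted p = 0.200). The region on the plus strand of chromosome 6 from 4697544 to 4710387 had more treated than untreated sites, 16 against 13, and its summed score was 631 untreated and 2291 treated. Its log2 odds ratio was 2.42, and 1.80 with the raised minimum (Fisher exact adjusted p = 6.60e-04 and 0.0384). Another 3 regions among those with the most treated sites also gained share: 36 and 26 sites on the minus strand of chromosome 2 from 22442836 to 22445844, 24 and 19 on the plus strand of chromosome 19 from 44374188 to 44381333, and 31 and 20 on the plus strand of chromosome 11 from 50192483 to 50199916. Their log2 odds ratios were 1.67, 1.80 and 1.51, with Fisher exact adjusted p of 0.00103, 0.00360 and 0.0237. None of these 3 was called with the raised minimum, at 0.95, 0.93 and 0.71 (Fisher exact adjusted p = 0.196, 0.287 and 0.450).

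The loss with the lowest p was on the minus strand of chromosome 1 from 183830983 to 183948891, where 167 untreated sites stood against 5 treated ones, a log2 odds ratio of -2.81 (natural-log SE 0.43, Fisher exact adjusted p = 8.22e-08). Only 2 of its untreated sites and 1 of its treated sites scored at least 100. With the raised minimum, a part of it with 60 and 2 sites gave -3.46 (Fisher exact adjusted p = 6.11e-06). A region on the minus strand of chromosome 10 from 62267625 to 62355464 went from 70 sites to 1, with a log2 odds ratio of -3.43 (natural-log SE 0.83, Fisher exact adjusted p = 6.60e-04), and with the raised minimum a part of it held 20 and 0 sites (Fisher exact adjusted p = 0.0212). On chromosome 7, from 140177558 to 140313795 on the minus strand, 134 untreated and 8 treated sites were listed, and on chromosome 19, from 4758489 to 4811440 on the minus strand, 125 and 8. Their log2 odds ratios were -1.86 and -1.76, with Fisher exact adjusted p of 6.60e-04 and 0.00173. With the raised minimum the chromosome 7 region fell into parts of which none was called, the lowest Fisher exact adjusted p being 0.0520 for a part with 43 and 6 sites and a log2 odds ratio of -1.60. The chromosome 19 region then gave -1.71 from 61 and 8 sites (Fisher exact adjusted p = 0.00733). The minus strand of chromosome 9 from 39998702 to 40045825 held 53 untreated sites and the plus strand of chromosome 2 from 162881521 to 162907740 held 39, and both are listed with 0 treated sites (Fisher exact adjusted p = 0.00115 and 0.0199). They held 29 and 23 untreated sites with the raised minimum (Fisher exact adjusted p = 0.00154 and 0.0106).

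Other site-rich regions did not pass the test. The plus strand of chromosome X from 166407841 to 166428656 held 132 untreated and 39 treated sites (Fisher exact adjusted p = 0.665), and the plus strand of chromosome 13 from 44826790 to 44903136 held 93 and 8 (Fisher exact adjusted p = 0.103, and 0.00690 for its part from 44826790 to 44880521 with the raised minimum). Chromosome 1 from 134876385 to 134915377 on the minus strand held 87 and 10, and chromosome 6 from 122677847 to 122692532 on the minus strand held 42 and 18 (Fisher exact adjusted p = 0.345 for both). Another 3 regions, with no treated site, also missed the threshold: 30 untreated sites on the plus strand of chromosome 4 from 145262370 to 145294098, 26 on its minus strand from 146981737 to 147014558, and 25 on the minus strand of chromosome 6 from 122268427 to 122289356. Their Fisher exact adjusted p-values were 0.0890, 0.180 and 0.180, and for the last, up to 122289156, 0.0347 with the raised minimum.

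Regions seen only after retinoic acid were small. The largest held 6 treated sites each, on the plus strand of chromosome 6 from 30690352 to 30698047 and on the minus strand of chromosome 1 from 170309218 to 170316204. On the minus strand of chromosome 13, 4 sites lay from 28942659 to 28951564 and 3 from 29041153 to 29042869, and on the minus strand of chromosome 11, 3 lay from 76147380 to 76161960. All 5 held too few sites to be tested.

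**Figure D3:**
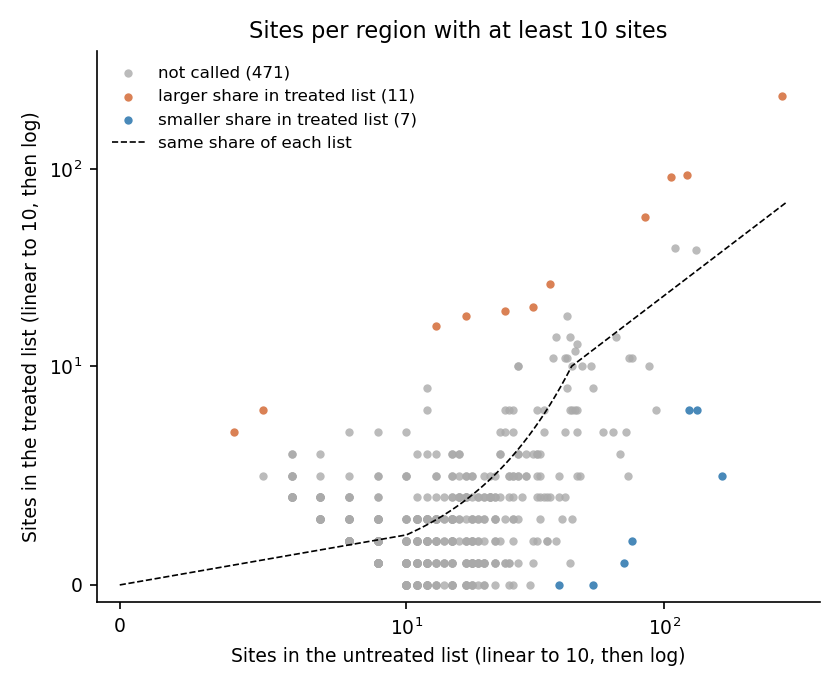
Sites in the untreated list (horizontal axis) and the treated list (vertical axis) for each of the 489 regions with at least 10 sites, both axes linear up to 10 and logarithmic above. The dashed line marks the same share of each list, with the 11 called regions of larger treated share above it and the 7 of smaller share below it.

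These region tests treat sites of 1 transcript as independent, which they are not, so they rank regions and their p-values are too small. Among sites with a score of at least 100, 31 regions were tested by Fisher exact test and 0 passed in either direction, with 4 at p under 0.05 before adjustment. Each of the 7 regions with a smaller share held fewer than 10 sites at that score, so none of the 7 was tested there. Some of the 11 with a larger share were left out for the same reason. The gains with the lowest p kept enough sites to be tested at that score, and none of them passed. The plus strand of the mitochondrial chromosome kept 208 untreated and 163 treated sites. The chromosome 17 region from 39979968 kept 106 and 91, and the chromosome 19 region from 5796096 kept 116 and 82. With the raised minimum, 4 gains and 9 losses were called, of which all 4 and 5 of the 9 overlapped the 11 and 7 above.

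By chromosome, the mitochondrial chromosome stood apart. It held 396 untreated sites (1.69% of the list, 1.53 to 1.87) and 275 treated sites (5.14%, 4.57 to 5.77), an odds ratio of 3.15 (2.68 to 3.69, two-sided Fisher exact adjusted p = 9.41e-41 over 22 chromosomes). Its share of the summed score went the other way, from 2.91% to 2.33%. That share depends on few sites, since the 10 highest-scored carried 24.9% of the untreated and 34.6% of the treated sum. Shares rose on chromosome 19, from 3.70% to 4.67%, and on chromosome 17, from 3.86% to 4.81% (Fisher exact adjusted p = 0.00817 and 0.00989). They fell on chromosome 7, from 5.65% to 4.45%, and on chromosome 4, from 6.91% to 5.93% (Fisher exact adjusted p = 0.00426 and 0.0407). With the 18 called regions taken out, chromosome 17 held 3.62% and 3.51%, chromosome 19 held 2.70% and 2.75%, and 0 of 22 chromosomes passed, with 1, the mitochondrial chromosome, at p under 0.05 before adjustment in the Fisher exact test. The regions taken out were chosen by the same test, so this says where the differences lay and does not test the chromosomes anew. On chromosome 4, which held none of those regions, only the list totals changed (Fisher exact adjusted p = 0.627). With a score of at least 100, the mitochondrial share was 12.8% untreated and 16.1% treated, and its odds ratio was 1.31 (1.05 to 1.62).

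Most mitochondrial contacts lay on the sense strand of messenger and ribosomal RNA genes. The plus strand from position 10 to 15390 held 286 untreated and 235 treated sites, a log2 odds ratio of 1.89 (natural-log SE 0.09, Fisher exact adjusted p = 1.03e-41). With the raised minimum it was 0.89 from 285 and 234 sites (Fisher exact adjusted p = 3.56e-09). The minus strand from 920 to 16190 held 110 and 40 (Fisher exact adjusted p = 0.255). Within the mitochondrial sites, the minus strand went from 27.8% (23.4 to 32.5) to 14.5% (10.6 to 19.3), an odds ratio of 0.443 (0.289 to 0.670, two-sided Fisher exact p = 4.74e-05). With a score of at least 100 it held 34 of 242 untreated sites and 12 of 175 treated sites. Sites antisense to a gene went from 24.0% to 13.1%, an odds ratio of 0.478 (Fisher exact adjusted p = 0.00249 over 5 classes). Untreated antisense sites had a median score of 39, against 162 in messenger and 1908 in ribosomal RNA. The antisense share was not tested among high-scored sites, so a loss of low-scored sites stays open for it. Messenger RNA held 60.6% and 66.9% of sites and ribosomal RNA held 10.4% and 16.4%, neither past the threshold (Fisher exact adjusted p = 0.173 and 0.0639). Ribosomal RNA carried 55.9% and 62.3% of the mitochondrial score.

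All 13 mitochondrial messenger RNA genes and both ribosomal RNA genes held a site in each list, while 10 of 22 transfer RNA genes did untreated and 6 did treated. In all, 25 of 37 genes held a site untreated and 21 treated, with 18 in both. By untreated sites, the genes with the most were mt-Co1, a subunit of cytochrome c oxidase, with 44 untreated and 35 treated sites, and mt-Nd5, a subunit of respiratory complex I, with 40 and 21. Next came mt-Nd4, another complex I subunit, with 26 and 23, and mt-Cytb, the cytochrome b of complex III, with 26 and 20. The small ribosomal RNA mt-Rnr1 had 21 and 22 sites with summed scores of 56885 and 40644, and the large ribosomal RNA mt-Rnr2 had 20 and 23 sites with 50103 and 27619. By treated sites, mt-Co1 was followed by mt-Nd4, mt-Rnr2, mt-Rnr1 and then mt-Nd5. Of 13 genes tested for a changed share of mitochondrial sites, 0 passed the Fisher exact test, and 0 had p under 0.05 before adjustment. Of the mitochondrial sites, 47.2% untreated and 69.8% treated were shared with the other list.

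**Figure D4:**
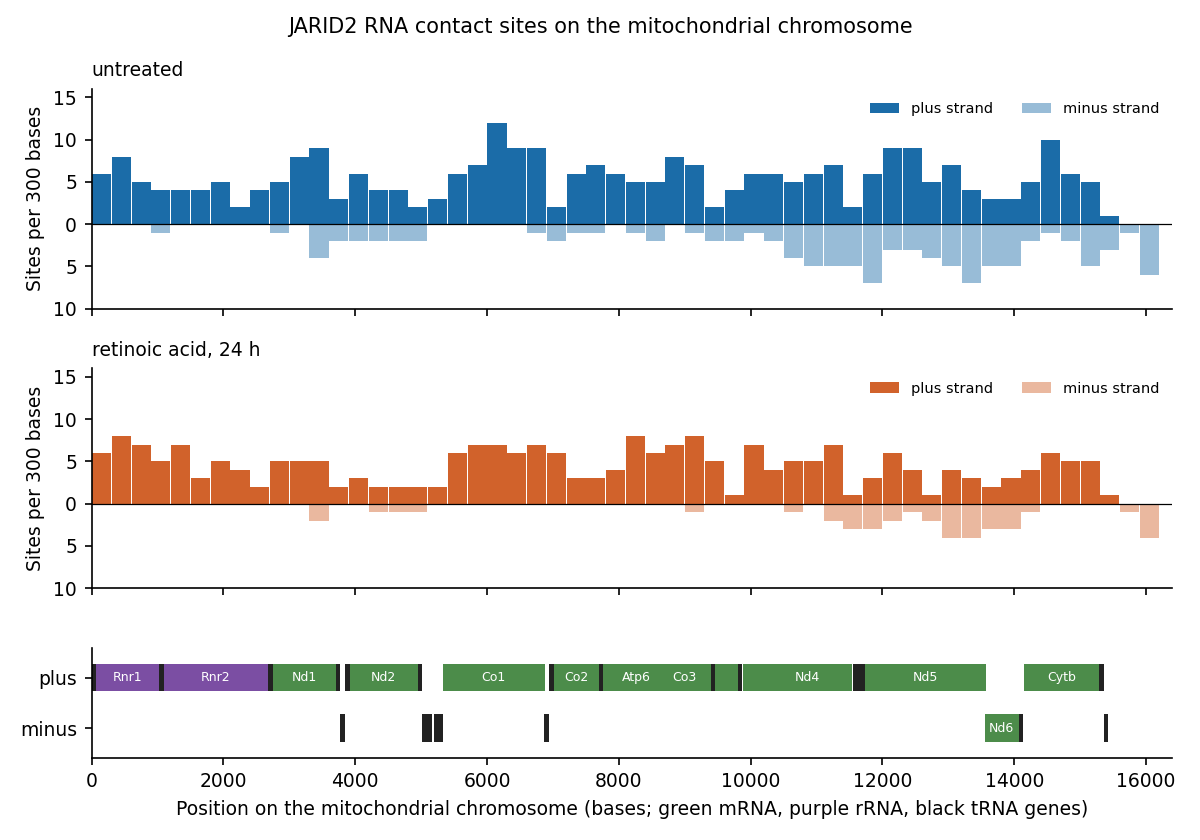
JARID2 RNA contact sites per 300 bases (vertical axes, plus strand upward and minus strand downward) along the mitochondrial chromosome (position in bases) for the untreated and retinoic acid lists, above the annotated genes. The minus strand held 110 of 396 untreated sites and 40 of 275 treated sites.

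Crosslinks of 4-thiouridine lie at U, read as T in the reference sequence. This was checked for mitochondrial sites only, as no nuclear sequence of the mm9 build was used. All 380 untreated and 269 treated mitochondrial sites that lay on known transcript sequence held a T on the RNA strand, while coordinates shifted by 3 to 500 bases gave 96.3% and 95.8% on average and reached 100% at 0 of 996 shifts. The T content of these untreated sites was 30.7%, against 30.6% in flanks of the same length, and that of these treated sites was 31.4%, against 29.8%.

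Meg3, Rian, Mirg and Jarid2, set to be named whatever their values, could not be matched to regions, because their mm9 positions were not among the sources used. All sites were kept, so regions given above by coordinates may cover these genes. Which of them do was not determined.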

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

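Score minimums, the removal of the region with the most sites from the overlap, and a treated minimum of 10 together with an untreated minimum of 18.0, called the raised minimum, were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the lists pool libraries b1 to b3 and hold no values per library, and leaving out each library could not be run for the same reason. For the mitochondrial genes, an exons-only count gives no value of its own, as they have no introns. The nuclear gene lists, the stratified test of gene lists and shares by nuclear gene class were not run, for lack of an mm9 annotation. The share of treated sites that overlapped untreated ones stayed above local chance under all 8 alternatives tried, from 15.8% with a reciprocal overlap to 65.7% at a score of at least 100. Mitochondrial genes with at least 2 sites numbered 19 untreated and 16 treated. The ratio of sites fell to 1.74 at a score of at least 100 and 1.53 at 1000, and to 2.21 with the raised minimum. Regions in both lists, untreated only and treated only numbered 619, 2499 and 117 with at least 2 sites, 990, 3917 and 491 in the higher-scored 50% of each list, and 349, 488 and 140 at a score of at least 100, as the construction of these alternatives leaves fewer sites. Untreated-only and treated-only regions numbered 13102 and 2157 with gaps of up to 1 kb, and 2831 and 573 with gaps of up to 100 kb, which splits or joins regions by construction. Treated sites shared at equal list length rose to 22.5% with the highest-scored untreated sites. Regions with a larger and a smaller treated share numbered 0 and 0 among 31 tested at a score of at least 100 (4 at p under 0.05 before adjustment in the Fisher exact test). None of the 7 regions with a smaller share in the main test had the 10 sites needed to be tested at that score. With the raised minimum, which changes both lists, regions with a larger treated share numbered 4 while those with a smaller share numbered 9, and in the higher-scored 50% of each list those with a smaller share fell to 2, and for both settings the cause was not tested. The mitochondrial share, untreated and treated, was 0.0241% and 0.0641% with each region counted once, 3.12% and 9.76% in the higher-scored 50% of each list, and 12.8% and 16.1% at a score of at least 100, and the untreated share was 3.35% with the raised minimum. It was higher in the treated list under these settings except that, with each region counted once, the same 2 regions stand over lists of different length and the values say nothing about the share. Read depth is unknown, so what it limits was not measured directly. The raised minimum stands in for it only if the score scales with depth.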

Other observations

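The values of single regions in this paragraph and the next, the tests with score minimums raised for the untreated list and the test of lower depth as the whole cause were chosen after the result was seen, and the explanation by shared reads was narrowed to reads listed at both places after its test was run. Among the 12 regions with the most score in either list, 4 places carried at least 10 times as much score in 1 list as in the other. The plus strand of chromosome 16 from 17222305 to 17222608 held 5 untreated sites with 4.23% of the untreated score, the highest at 260828, and no treated site lay within 1 kb on either strand. On the plus strand of chromosome 9, 1 site from 17792232 to 17792258 scored 126031 untreated and 2958 treated, and on the minus strand of chromosome 4, 1 site from 121870910 to 121870941 scored 100722 and 7299. On the plus strand of chromosome 5, the region from 137408821 to 137409764 summed to 11 untreated and 98160 treated. The lists hold no values per library, so whether 1 library carried any of these was not tested.

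Outside the naming rule, 4 more regions were called. On the plus strand of chromosome 6, from 3150785 to 3151645, 17 untreated and 18 treated sites gave a log2 odds ratio of 2.21 (Fisher exact adjusted p = 6.60e-04). All 17 and all 18 had a score of at least 100. On the plus strand of chromosome 12, from 110865388 to 110979270, 75 untreated sites stood against 2 treated ones, with a log2 odds ratio of -2.79 (Fisher exact adjusted p = 0.00173). The small regions on the minus strand of chromosome 13 from 63609764 to 63612368, with 5 and 8 sites, and on the plus strand of chromosome 10 from 98726011 to 98730001, with 4 and 7, also gained share (Fisher exact adjusted p = 0.0230 and 0.0342). With treated sites scored at least 10 and untreated sites scored at least 18.0, none of these 4 was called: the first gave 1.23 and a part of the chromosome 12 region -2.02 on the log2 scale (Fisher exact adjusted p = 0.165 and 0.160), and the small regions held too few sites to be tested. The treated-only neighbours on the minus strand of chromosome 13 between 28942659 and 29042869 held 7 treated sites with a summed score of 317 and 0 untreated sites on either strand.

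The treated list was shorter, and lower depth of the treated libraries is a candidate explanation for part of that. At loci with a score of at least 1000, the median log2 score ratio was -1.19 for loci picked from the untreated list and -0.50 for loci picked from the treated list. Of these loci, 249 of 300 untreated and 189 of 202 treated had a site in the other list. The others were kept, with absent loci counted as lowest. The mean of the 2 medians was -0.85 (bootstrap interval of the mean -0.96 to -0.70), though weaker contact of JARID2 with RNA would lower scores too. With treated sites scored at least 10, 5142 of 5348, set against untreated sites scored at least 18.0, as the mean fold requires, the untreated list stayed 2.21 times as long (1.93 to 2.38 over the bootstrap interval, and 1.61 and 2.77 with either median), which argues against depth as the whole cause if the score scales with depth. Among treated sites scored at least 100 and untreated sites scored at least 180, the ratio was 1.19 (1.15 to 1.27, and 1.04 and 1.38 with either median), so there depth as the whole cause stays open and the excess lay among low-scored sites. A change in contacts after retinoic acid stays open, as does a difference in how the lists were called.

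The higher mitochondrial share of sites after retinoic acid may in large part come from the loss of low-scored sites elsewhere. Among sites with a score of at least 100 the odds ratio was 1.31 (1.05 to 1.62), down from 3.15 over all sites, and with the untreated minimum also raised by the depth fold it was 1.36 (1.07 to 1.72). Both intervals lie above 1, but their lower limits are close to it. They treat sites of 1 transcript as independent, which makes them too narrow. Whether these losses account for the whole difference in counts therefore stays open. The share of summed score was lower in the treated list, so a gain of mitochondrial contact is not shown by the score. A few high-scored sites elsewhere weigh on that share. A biological difference, such as more mitochondrial RNA in treated cells, was not tested.

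A gain in share was called for 10 nuclear regions besides the plus strand of the mitochondrial chromosome, and reads shared between the mitochondrial chromosome and nuclear copies of it, listed at both places, could give that. Sites were counted as coinciding when both their first and last base matched after a shift of coordinates. In the 10 called nuclear regions at most 3 sites did so at 1 shift, the same number as in the 477 other regions tested. This argues against double listing of sites with the same ends. Sites whose ends differ between the copies were not counted, so the test cannot decide on those. It says nothing about reads placed at 1 copy only, which stays open without the mm9 sequence. The loss of low-scored sites elsewhere, considered above for the mitochondrial share, also stays open for these regions. With the raised minimum 4 of the 11 gains were called, the mitochondrial plus strand among them. At a score of at least 100, 0 of 31 regions tested passed. No biological explanation was tested.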
